A study of Caenorhabditis elegans with 6 samples.

How the data were processed

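Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the nuclear receptor NHR-25 sits on the Caenorhabditis elegans genome at the L2 larval stage. Per the labels, the worms were hermaphrodites of strain OP33, which carries an integrated nhr-25 transgene with a GFP and FLAG tag in an unc-119 background. They were raised on HB101 bacteria at 20 °C and fixed with 2% formaldehyde. The chromatin was sonicated and the tagged protein was collected with antibodies against GFP, and a part of each chromatin extract was kept as input. The 6 samples fall into 3 ChIP and 3 input replicates, grouped by their titles. The labels do not say whether the replicates came from separate worm cultures, so any spread between them may be technical.

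Peak lists of the 3 ChIP replicates and 1 combined list for the series were used. The input samples were not analysed here. Per the file headers, coordinates are on the WormBase release WS220, and the source field of each peak names the SPP peak caller and the IDR (irreproducible discovery rate) procedure. The aligner, the filters, the control libraries, the IDR threshold and the way the replicates were merged into the combined list are not given in the sources used here. The value of each peak in the deposited lists, in column 6, is a −log10 of a false discovery rate (FDR) estimate. The unit was read from the values. In each replicate list the highest value is shared by many peaks and equals the −log10 of 0.5 divided by their number, the value an FDR estimate takes when no control peak is as high. The count it implies equals the count present in all 3 replicate lists and exceeds it by 13 in the combined list. This ceiling lies at 3.93, 3.73 and 3.92 in replicates 1, 2 and 3 and at 3.96 in the combined list, and it leaves 75.4% of the combined peaks tied. The peak numbers that the authors gave run without a gap from 1, list the peaks at the ceiling first and follow the falling value below it (Spearman's rho 0.972 in the combined list). They were therefore used to rank peaks within a list. The lists hold no read counts, so the sequencing depth is unknown here.

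The replicate lists run far below usual thresholds, down to values that stand for an FDR of 0.843, 0.990 and 0.888. Each was therefore reduced to its 6029 first peaks, the size of the combined list, and these are called top lists. Peaks were called shared when they overlapped by at least 1 bp. Random expectations came from 1000 placements of the peaks at uniform positions on their own chromosomes, with widths kept, and permutation p-values were two-sided with a smallest possible value of 0.001. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Strength was compared between replicates by Spearman's rho across combined peaks, which are not independent replicates, so no p-value was computed. For this comparison the full replicate lists were used, not the top lists. Peaks per chromosome were tested by a chi-square test against chromosome length and by an exact two-sided binomial test of X against the 5 autosomes. The length of a chromosome was taken as the last base that any deposited peak reached. These comparisons were fixed before the data were examined, apart from the chromosome lengths. The plan asked for lengths of the WS220 build and left the chromosome comparison out without them. Taking the last base reached was a departure from the plan, drawn from the data. Draws of peaks from each replicate's own full list, reported below, were not in the plan either.

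Of the comparisons fixed beforehand, 6 were left out. The gene table used here is on assembly WBcel235 and no genome sequence of WS220 was used; coordinates of different builds were not mixed. The shares of peaks in promoters and coding exons, the NR5 receptor motif at peak centres and by rank, the control motifs and the fixed gene lists were therefore not analysed, and no gene, nhr-25 included, is named for any peak. The rule for named items was written as the 10 combined peaks with the highest value, with ties broken by the q or p value and then by position; because of the ceiling, the 10 lowest peak numbers were taken instead, a change made after the files were seen. Other choices made after the data were seen are the comparison of the central 50% with the outer parts of chromosomes, the counts in 1-Mb bins, the distances between neighbouring regions, the windows of 30 kb, the gaps, the broad regions and the search for strong peaks outside the combined list. Overlapping peaks were joined into regions for the distances, windows, gaps and broad regions, while the bins and the parts of chromosomes were counted in peaks. Bins were compared by permutation tests of the mean, exact where a group had under 10 bins and with 100000 resamples otherwise, and regions were also placed at random within their own 1-Mb bins.

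Overlap and density scripts were tested on simulated lists of 6029 peaks. Lists made to share 0, 30 and 70% of their peaks gave overlaps of 5.22, 33.7 and 71.6%. Simulated X to autosome density ratios of 1, 1.2 and 1.5 were recovered as 1.00, 1.19 and 1.50, with a binomial p under 0.05 in 8, 100 and 100 of 100 simulations. Simulated peaks were placed independently and uniformly along each chromosome, whereas the observed peaks lie unevenly and close together. The simulations therefore do not show how often the binomial test passes by accident on the observed lists. The alternatives tried were a reciprocal overlap of 50%, the first 3014 peaks, all deposited peaks, each replicate left out or taken alone, joined regions, and parts of the chromosomes; they used 200 random placements, or 20 for the reciprocal overlap. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.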

Results

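The series mapped binding regions of GFP-tagged NHR-25 in L2 larvae. NHR-25 is the worm member of the NR5 family of nuclear receptors, related to Drosophila FTZ-F1 and mammalian SF-1, and is known for roles in the epidermis and in molting. The combined list held 6029 peaks, all on the 6 nuclear chromosomes. They had a median width of 440 bp, formed 5720 separate regions and covered 2.26 Mb. Exactly 440 bp was the width of 66.2% of them. In replicates 1, 2 and 3, 97.4, 97.7 and 97.7% of the peaks were exactly 430, 430 and 450 bp wide. The width and the coverage therefore do not measure the extent of binding. The replicate lists held 30000, 29241 and 30000 peaks, of which 4248, 2662 and 4126 lay at the ceiling of the authors' value (mean 3679 ± 883, SD, n = 3). The numbers at the ceiling differed between all 3 lists, so none was a copy of another. Positions are WS220 coordinates.

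The first question was which sites carried the strongest signal and whether every replicate placed them alike. The first peak of the combined list lay on chromosome III from 3867312 to 3867773 and was number 1 in replicates 1 and 2 and number 2 in replicate 3. The next lay on chromosome II from 10563335 to 10563708, numbered 2, 3 and 4 in replicates 1, 2 and 3, and on chromosome IV from 4749853 to 4750266, numbered 3, 4 and 1. Chromosome III held 5 of the first 10 peaks, the others of them at 10758937 to 10759374, 7854425 to 7854852, 4899665 to 4900127 and 13643447 to 13643829. The remaining 3 were on chromosome IV from 654744 to 655119, on chromosome II from 8561184 to 8561590 and on chromosome I from 9625871 to 9626242. Each of the 10 was among the first 18 peaks of every replicate, and no replicate midpoint lay more than 17.5 bp from the combined one. The 10 were picked by their number in the combined list, which belongs to the same ChIP samples. Their high places in the replicates are therefore no independent evidence. None of the 10 was on chromosome V or X, although X held 114 of the first 500 peaks (22.8%).

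The replicates shared most of their top peaks. Of the 6029 first peaks of one replicate, 69.9% overlapped a top peak of the other for replicates 1 and 2, 69.9% for replicates 1 and 3, and 70.0% for replicates 2 and 3 (mean 70.0 ± 0.0648%, SD over 3 pairs that share replicates). Random placement gave means of 5.04, 5.12 and 5.19% and never more than 6.11% (permutation p = 0.001 for each pair, the smallest that 1000 placements can give). Drawing 6029 peaks at random from each replicate's own full list gave means of 14.1, 14.8 and 14.2% and at most 15.6% (permutation p = 0.005 for each pair, the smallest that 200 draws can give). Overlapping top peaks had midpoints a median of 40, 39 and 42 bp apart.

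Most combined peaks were found in the top lists, and how often depended on their place in the combined list. All of the first 1000 combined peaks overlapped a top peak in every replicate, and 98.0% of those numbered 1001 to 2000 did. The share fell to 79.4% at 2001 to 3000, 41.1% at 3001 to 4000, 15.3% at 4001 to 5000 and 8.84% at 5001 to 6029, where 131 peaks (12.7%) overlapped no top list. Over the whole list, 3429 of 6029 peaks (56.9%, exact 95% interval 55.6 to 58.1%) were in every replicate's top list. Random placement gave a mean of 2.42% and a maximum of 3.07% (permutation p = 0.001, the smallest possible), but the combined list belongs to the same ChIP samples, so an excess over random placement was set in advance and is no independent evidence. Replicates 1, 2 and 3 contained 80.2, 77.8 and 78.1% of the combined peaks, and 4921 peaks (81.6%) were in at least 2 of them. The share in every replicate was 35.5% when a reciprocal overlap of 50% was required, 92.4% for the first 3014 combined peaks and 96.0% when all deposited replicate peaks were used. With all deposited peaks it was 99.3% at 2001 to 3000 and still 86.4% at 5001 to 6029. Most of the fall along the combined list therefore came with the cut of the top lists.

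**Figure D1:**
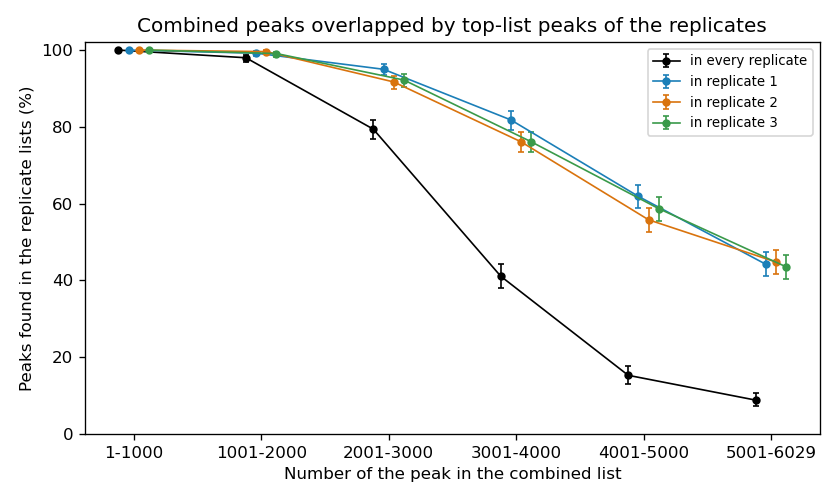
Share of combined peaks, in percent, that overlapped a peak of the replicates' top lists (vertical axis), by the number of the peak in the combined list (horizontal axis); points are shares in each replicate and in every replicate, and bars are exact 95% intervals. The share in every replicate was 100% for peaks 1 to 1000 and 8.84% for peaks 5001 to 6029.

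Combined peaks that were strong in one replicate tended to be strong in the others, although the authors' value showed this only in part because of its ceiling. Across combined peaks, Spearman's rho of the value was 0.416 between replicates 1 and 2, 0.336 between 1 and 3 and 0.437 between 2 and 3 (mean 0.396 ± 0.0532, SD over 3 pairs). With the peak number in place of the value, rho was 0.680, 0.676 and 0.676 (mean 0.677), and among combined peaks at the ceiling, whose values are tied in the combined list, its mean was 0.675. For the first 3014 combined peaks the mean rho of the value was 0.034. These are correlations across the 5872, 5887 and 5841 combined peaks that overlapped a peak in both full replicate lists. Such peaks are not independent replicates. The combined list belongs to the same ChIP samples and its source field names the IDR procedure. Its peaks may therefore have been selected for agreement, and peaks outside it were not compared in this way.

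NHR-25::GFP peaks were unevenly spread over the chromosomes. Chromosome III had the highest density, 71.8 peaks per Mb (990 peaks), followed by X with 67.7 (1200 peaks), I with 64.6 (974) and II with 62.5 (955). Chromosome IV had 52.5 peaks per Mb (919) and V the lowest density, 47.4 (991). The counts departed from chromosome length (chi-square 128, p = 5.2e-26). X held 19.9% of the peaks (exact 95% interval 18.9 to 20.9%) on 17.7% of the span, a density 1.16 times that of the autosomes (exact two-sided binomial p = 7.6e-06; 1.17 ± 0.0231, SD, n = 3, in the replicates' top lists). With all deposited peaks of the replicates the direction turned in replicates 1 and 3, with ratios of 0.917 (exact binomial p = 2.0e-08) and 0.943 (exact binomial p = 1.2e-04), and the ratio was 1.001 in replicate 2 (exact binomial p = 0.939). These tests count peaks as independent. In 1-Mb bins the difference did not pass: 17 bins of X held 67.5 ± 16.6 peaks and 80 autosomal bins 58.6 ± 25.8 (SD; permutation p = 0.176, two-sided).

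The autosomes were denser in their middles than in their outer parts, and X was much less so. Of 4829 autosomal peaks, 3125 (64.7%, exact 95% interval 63.3 to 66.1%) lay in the central 50% of their chromosome, as did 65.2 ± 0.776% (SD, n = 3) in the replicates' top lists. Chromosome V was the most uneven, with 73.5% of its peaks in the central part, 69.6 peaks per Mb there and 25.1 in the outer parts. The shares were 63.0% on I, 63.7% on II, 61.6% on III and 61.5% on IV. Left and right ends were not always alike. On II the outer 1-Mb bins held 38, 16, 23 and 21 peaks on the left and 103, 53, 58 and 62 on the right. On III they held 49, 29 and 34 on the left and 83, 53 and 62 on the right. On X the share was 53.7% (50.8 to 56.5%; Fisher's exact test of the autosomes against X, odds ratio 1.58, p = 2.4e-12). By 1-Mb bins, autosomal central parts held 75.4 ± 18.9 peaks per bin (41 bins) and outer parts 40.9 ± 19.6 (39 bins; SD; permutation p = 1e-05, the smallest that 100000 resamples can give), while the corresponding values on X were 70.4 ± 7.16 (9 bins) and 64.2 ± 23.5 (8 bins; exact permutation p = 0.478).

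X and the autosomes thus differed at the chromosome ends, with no detectable difference in the middles. In the outer parts X had 62.8 peaks per Mb and the autosomes 41.3, a ratio of 1.52 (1.51 ± 0.0235, SD, n = 3, in the replicates), and the bins there differed (exact permutation p = 0.00511). Single autosomes ranged there from 25.1 peaks per Mb on V to 55.1 on III, all below X. On X the outer bins held 38, 37, 78 and 45 peaks at the left end and 105, 72, 76 and 63 at the right end. The higher counts of X thus lay mostly at its right end, and its ends were not tested apart. The bin tests treat neighbouring bins as independent, and X is a single chromosome, so they do not measure the spread between chromosomes. In the central parts X had 72.7 peaks per Mb and the autosomes 75.7, a ratio of 0.960 (exact binomial p = 0.359; bins, exact permutation p = 0.446). The densest bin was at 11 to 12 Mb on V, followed by the bins centred at 7.5 and 9.5 Mb on I with 109 peaks each; the densest of X was at 13 to 14 Mb. The sparsest bin of V, starting at 17 Mb, held 6 peaks, and the sparsest bin of X held 37.

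**Figure D2:**
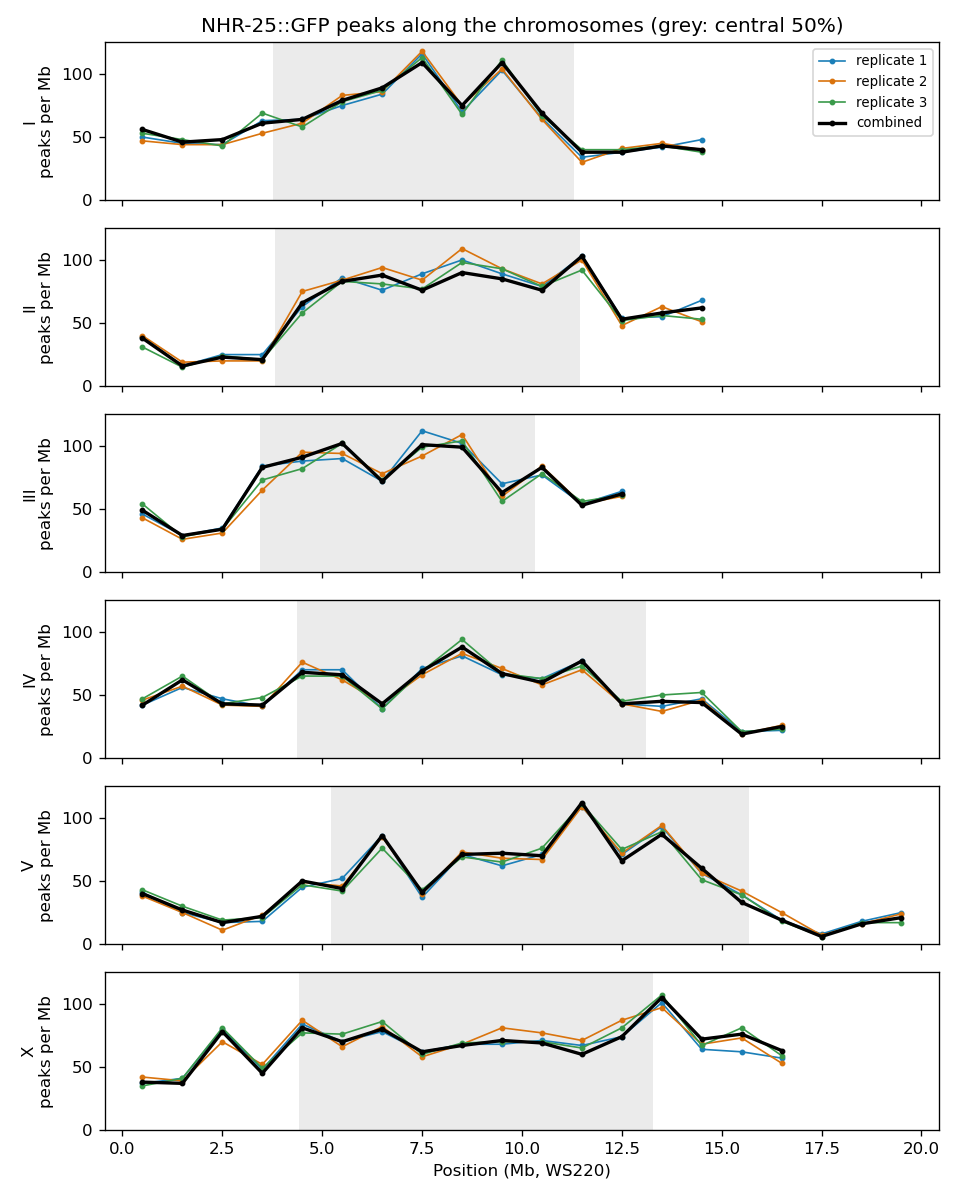
Peaks per Mb in 1-Mb bins (vertical axis) against position in Mb on WS220 (horizontal axis) for chromosomes I to V and X, in the combined list (black) and in the top lists of the 3 replicates (blue, orange and green); grey marks the central 50%. Chromosome V falls to 6 peaks in its sparsest combined bin, while the lowest bin of X holds 37.

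Binding regions lay close together more often than random placement gave. Of the 5720 combined regions, 42.2% had another region's midpoint within 2000 bp, as did 40.9 ± 0.877% (SD, n = 3) in the replicates' top lists. Placement at random within 1-Mb bins, which keeps the broad density, gave a mean of 22.6% and a maximum of 25.1% (permutation p = 0.001, the smallest possible). Among the first 3014 peaks the share was 25.6%, with permutation p = 0.005 against their own random placements. The densest 30-kb window was on chromosome II from 6821204 to 6849605, with 23 regions, 20 of them at the ceiling, and 20 regions in each replicate's top list, counted by their midpoints. The next were on X from 12989056 to 13016761 with 20 regions (15, 16 and 15 in replicates 1, 2 and 3) and on V from 6221033 to 6247995 with 17 (15, 17 and 15). No window exceeded 15 regions in the random placements within bins. The window on X from 6723049 to 6750597 had 15 regions, of which 8 were among the first 500 peaks.

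**Figure D3:**
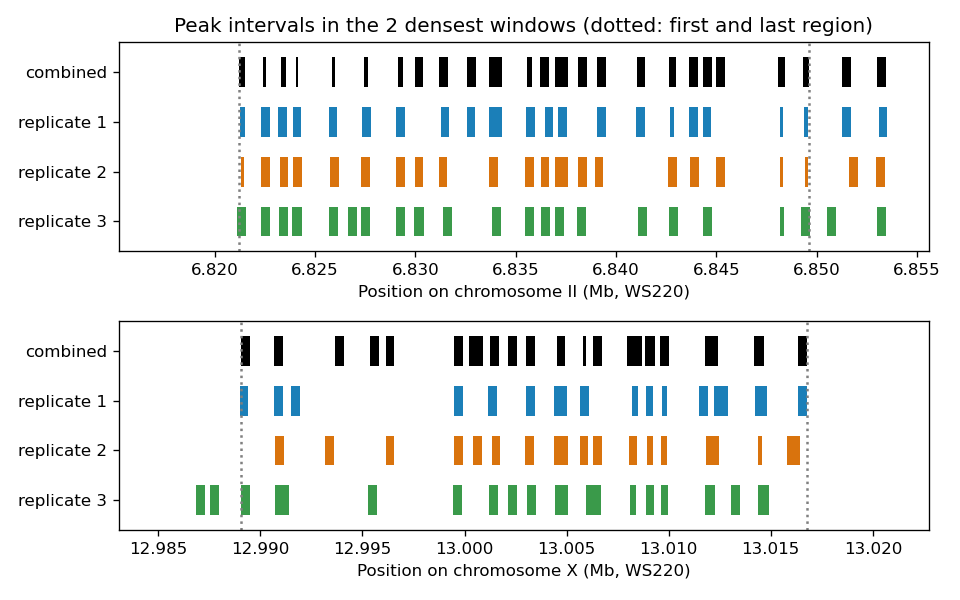
Peak intervals of the combined list and of the top lists of the 3 replicates (rows on the vertical axis) against position in Mb on WS220 (horizontal axis) in the densest windows of chromosomes II and X; dotted lines mark the starts of the first and ends of the last region. The window on II holds 23 combined regions and 20 in each replicate, and the window on X holds 20 combined regions.

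The longest stretch without a combined peak was on chromosome V from 16965967 to 17857834, 892 kb, against a maximum of 764 kb in random placements within bins. Replicates 1, 2 and 3 had 1, 0 and 0 top peaks there, and 40, 36 and 35 peaks in their full lists. Gaps of 499 kb on II from 1320804 to 1819903 and 482 kb on V from 18087190 to 18569497 came next, both shorter than that maximum. The gap on II held 3, 3 and 2 top peaks of replicates 1, 2 and 3, and this gap on V held 1, 1 and 0. Another gap of 400 kb lay right behind the one on II, from 1820344 to 2219865. Of 10 gaps over 300 kb, 7 were on V and 0 on X, whose longest was 231 kb; the median gap was 5.21 kb.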

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

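The tests for peaks on the mitochondrial genome and for strong peaks outside the combined list were all chosen after the results had been seen.

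The combined list has no mitochondrial peak, but the replicate lists have 15, 24 and 24 in replicates 1, 2 and 3. Of them 9, 17 and 11 were within the top lists and so entered the overlap of replicates, while the comparisons of chromosomes left them out. Of all these, 8, 15 and 7 were at the ceiling, and the best were numbered 158, 59 and 40. Joined, they covered positions 1 to 13379 of the mitochondrial genome in replicate 1, 2 to 10634, 10689 to 13359 and 13686 to 13873 in replicate 2, and 1 to 13371 and 13610 to 13889 in replicate 3. The input samples were not analysed here, so the level without immunoprecipitation was not compared and no biological explanation was tested.

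A few sites were strong in every replicate and absent from the combined list. Of 2088 replicate 1 peaks at the ceiling that overlapped ceiling peaks in replicates 2 and 3, 29 (1.39%) overlapped no combined peak. All 29 were on nuclear chromosomes, and the mitochondrial peaks described above, which the combined list also lacks, are not among them. A candidate explanation is ranks near the end of the combined list. But 2 of the peaks were among the first 1000 in all 3 replicates, which argues against it for these 2. It is not excluded, since the rank of an absent peak in the combined list is unknown, and it stays open for the others. These 2 lie on X from 12480585 to 12480692, numbered 797, 603 and 807, and on V from 8500297 to 8500726, numbered 964, 901 and 891. Intervals shifted to a neighbouring call are argued against as the whole source, since only 5 of the 29 had a combined midpoint within 1 kb and the median distance was 13.3 kb. A filter applied when the lists were combined stays open and was not tested, and the design gives no biological explanation to test.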

How the results depend on the processing

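The alternatives for the X ratio in full replicate lists, in peaks below the top lists and in parts of the chromosomes, those with joined regions, and all those for central parts and neighbouring regions were chosen after seeing the data. Of 42 alternatives over 6 results, 32 kept the direction and the side of the threshold, or moved by less than the spread between replicate pairs. The 32 include 7 for combined peaks in every replicate, whose excess over random placement was set in advance. For the replicate overlap and rank agreement, leaving 1 replicate out only gives back a pair already reported. The count is therefore no measure of robustness by itself. The replicate overlap ranged from 58.0 to 73.2%, above random placement, and the share of combined peaks in every replicate from 35.5 to 96.0%; autosomal peaks in central parts ranged from 64.2 to 66.0%. Rank agreement moved to 0.677 with the peak number and to 0.034 in the first 3014 peaks, and ranged from 0.336 to 0.437 with 1 replicate left out. The 0.034 was computed from the replicates' own values, which have ceilings of their own. With the peak number, rho in the same 3014 peaks was 0.675 for replicates 1 and 2, 0.677 for 1 and 3 and 0.678 for 2 and 3. The higher density on X depended on which peaks were taken. Its ratio to the autosomes was 0.917, 1.001 and 0.943 with all deposited peaks of replicates 1, 2 and 3 (exact binomial p = 2.0e-08, 0.939 and 1.2e-04), and 0.863, 0.955 and 0.886 with the peaks below their top lists (exact binomial p = 3.8e-17, 0.00889 and 3.1e-12); the cause was not tested. In the central parts it was 0.960. No paired analysis was possible because the input samples that share replicate numbers with the ChIP samples were not analysed here. The alternatives listed for promoters, coding exons, motifs and gene lists were not run, since the annotation used here is of another build. The unknown depth and the ceiling limit any ranking by the authors' value.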

Other observations

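The descriptions of broad regions and the tests below were chosen after the data were seen, except that the predictions for crowded stretches of X and for a split broad signal on II were written before their tests were run.

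Broad regions of at least 1000 bp numbered 14 in the combined list. The widest lay on chromosome I from 5807654 to 5815422, a single interval of 7769 bp that is listed for 9 combined peaks. Replicate 3 likewise listed 1 interval of 7788 bp for 12 peaks, whereas replicates 1 and 2 had 13 and 14 different intervals of at most 430 bp there. Its best peaks were numbered 682, 1343 and 511 in replicates 1, 2 and 3. Next came chromosome I from 15064016 to 15067629, 3614 bp, which was 1 interval of 3497, 3539 and 3534 bp in the replicates. It lies close to the last base that any peak reached on I, 15068615; the right end of this chromosome is known to carry the ribosomal RNA gene array. The widest on chromosome II ran from 8418694 to 8421639 and from 9169837 to 9172214. Chromosome III had 3 of them, from 10904064 to 10905592, from 12425526 to 12426941 and from 12427284 to 12428558.

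X had more peaks per Mb than the autosomes. Calling that favours X at every strength would also raise the ratio among peaks below the top lists, but it was at most 0.955 in any replicate. Those peaks run down to an FDR of 0.843, 0.990 and 0.888 in replicates 1, 2 and 3. They cannot show whether calling favours X among the strong peaks only, so that stays open. A few crowded stretches of X predicted a share of occupied windows no higher on X than on the autosomes. Of 1771 windows of 10 kb on X, 35.5% held a region, and of 8251 on the autosomes, 32.7%. The ratio was 1.085 (Fisher's exact p = 0.026, with windows counted as independent). This argues only against crowding within 10 kb as the whole source. Longer crowded stretches would raise the share too and stay open. The bins of X centred at 13.5, 14.5, 15.5 and 16.5 Mb held 105, 72, 76 and 63 peaks. Peak-poor ends of the autosomes may account for the difference, since the ratio was 0.960 in the central parts of the chromosomes. Whether those ends lack binding sites, genes or mappable sequence was not tested, and the design gives no biological explanation to test.

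The densest window, on chromosome II, held 23 regions. A call list of 1 replicate is excluded as its source, because each replicate had at least 20 regions there and random placement within bins reached 15. For 1 broad signal split into many calls, joining regions within 1 kb left 8. This lay between the 3 or fewer that it predicted and the more than 15 that was set to exclude it. The limit of 15 came from regions that were not joined, so the 2 counts are not alike. By the joined count the window on X from 12989056 held more, 10. Separate sites and a split signal cannot be told apart without the read coverage. No biological explanation was tested.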
